A study of Mus musculus with 9 samples.

How the data were processed

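RNA from mouse testes on postnatal day 7 was sequenced as libraries enriched for mRNA with oligo(dT) beads, per the labels' protocols. The 9 libraries form 3 groups of 3 by their titles: wild type, Gm1142 knockout and double knockout of Gm1142 and Gm4779. The labels number the replicates 1 to 3 in each group and state no pairing, batch, litter or sex.

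The deposited table holds raw read counts per gene, in 1 column per library. The submitters' processing notes name cutadapt, Bowtie2, STAR and featureCounts and the genome build mm39, without versions. The strand setting, the annotation release and the treatment of reads that map to several places were not given in the sources used here. Each affects genes that overlap another gene or have near-identical copies, such as the mitochondrial genes with nuclear copies, globin genes, Y-linked genes with an X-linked relative and ribosomal protein genes with pseudogenes. Whole-number values with a different total in each column were checked to fit raw counts. The table lists 56691 genes by identifier, of which 52073 were paired with a symbol. Genes without a symbol held 0.411% to 0.510% of a library's counts.

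Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed the default filter by group (minimum count 10, minimum total 15), which left 17251. Library sizes were scaled by TMM, with factors from 0.856 to 1.07. A quasi-likelihood model with 1 term per group was fitted to the 9 libraries together, so that the groups share 1 estimate of the spread with 6 residual degrees of freedom, and each of 3 comparisons was tested with the quasi-likelihood F-test. The p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with an adjusted p under 0.05 were called, without a fold minimum. The standard error of a log2 fold change is its size divided by the square root of F. Levels are CPM values on TMM-scaled library sizes, given as mean ± SD of 3 libraries. For a gene with 0 counts in a group, the fold is a lower bound against a floor of 3 counts over the summed depth of that group. A floor of 3 counts in 1 library is 0.338 CPM in the deepest and 0.767 CPM in the library with the lowest scaled depth. Floors cover counting error only, and reads without molecular identifiers are not independent molecules.

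Before the data were examined, 31 gene lists were fixed: germ-cell stages and pathways, somatic cells of the testis, cells a dissection could bring along, sex-linked genes, and metabolic, stress and proliferation programmes. They hold 654 entries, of which 624 matched the table by symbol, 4 by an older name and 26 not at all, and 520 were tested. A list of replication-dependent histones had fewer than 5 tested genes and was not tested, which left 30. Lists were tested with camera, which compares a list with all other genes, at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 30 lists. The same test with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were alternatives. Besides the count of members called over all genes, a count adjusted over the list alone is given.

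The rule for named genes was also fixed beforehand. It took the targeted genes. It took, per comparison, the 12 largest positive and 12 largest negative log2 fold changes among called genes whose groups do not overlap and whose higher group has at least 1 CPM, leaving out predicted-gene symbols and bare identifiers. It took up to 4 called members of each list, or the 3 with the smallest p of a called list without called members. Of the called genes the rule or a later choice named, 55 of 97 kept the call whichever library was left out in the first comparison, 7 of 14 in the double knockout against WT and 61 of 104 between the knockout groups. The text prints the most changed of them and the members of called lists. The nuclear copies Gm28438, Gm28437 and Gm10222, and Gm47283, Srsf6, Ezh2 and Prrc1, were added after their values were seen. A further gene chosen in the same way is not reported here.

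Alternatives fixed beforehand were DESeq2's size factors in the same fit, no filter and a stricter filter (at least 1 CPM in 3 libraries and 100 counts in total), DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, the replicate number as a block, a minimum absolute log2 fold change of 1, the other list tests, and leaving out each library in turn. Alternatives chosen after seeing the data were removal of mitochondrial genes and their 3 nuclear copies, removal of per-library trends on GC content and length (known for 97.4% of tested genes), thinning of all libraries to the shallowest, and a fit without replicate 2 of the Gm1142 knockout and of the double knockout, which lay farthest from their groups.

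The gene test was tested on simulated data drawn from the real means, dispersions and library sizes of 17251 genes, with 100 genes changed 2-fold and 100 changed 4-fold. For the Gm1142 knockout against WT it recovered 50% and 86%, with 14 false calls of 150. For the double knockout against WT it recovered 48% and 78%, with 7 false calls of 133, and between the knockout groups 53% and 82%, with 16 of 151. A simulated list of 25 genes shifted by 0.5 was called in each of the 3 comparisons, and none of 30 other lists was. Genes were drawn independently, so this does not test camera on lists whose genes vary together. In the double knockout against WT, the estimated correlation of the real lists ran from -0.104 (spermatid) to 0.721 (stroma and collagen). Comparisons that share a group were set against 20 simulations of unchanged groups that share it. Replicates were also checked for duplication: the chi-square per degree of freedom between libraries of a group was 3.82 to 11.0, so none was a copy of another.

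Coordinates, exonic lengths and the alignment of mitochondrial genes with their nuclear copies (Biopython 1.88) come from GENCODE release M21 on GRCm38. The count table was made on another build, so no position was carried between them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Reads, transcript isoforms and the sequence of the targeted alleles were not analysed here.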

Results

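Messenger RNA was sequenced from mouse testes on postnatal day 7, an age at which the seminiferous cords hold spermatogonia and immature Sertoli cells and the first germ cells approach meiosis. The 9 libraries fell into 3 groups of 3: wild type (WT), libraries labelled Gm1142 knockout, and libraries labelled as lacking both Gm1142 and Gm4779, called the double knockout below. Total gene counts per library were 4514237 to 5091624 in WT, 4597447 to 5243756 in the libraries labelled Gm1142 knockout and 4370124 to 8359594 in the double knockout, where replicate 2 was the deepest. Of the 56691 genes in the count table, 17251 had enough counts to be tested. Nothing in the labels states that the replicates came from separate animals or litters, so the p-values measure only the spread between these samples, which may be technical. The comparisons ask how the P7 testis transcriptome differs from WT when Gm1142 is targeted alone and when it is targeted together with Gm4779.

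The targeted genes were read first, in every library. They are neighbouring protein-coding genes on the X chromosome. In the GRCm38 annotation used as reference, Gm1142 (ENSMUSG00000046774.18, symbol 8030474K03Rik) lies at positions 101794656 to 101798642 on the plus strand with 2004 exonic bases. Gm4779 (ENSMUSG00000045010.15) lies at 101790053 to 101794423 on the minus strand with 2364 exonic bases, and 232 bases separate them. The submitters counted on mm39, so these positions describe the reference only. In the double knockout both genes had 0 counts in 3 of 3 libraries. With a floor of 3 counts over the group (0.162 CPM), WT was at least 60.5-fold higher for Gm1142 and at least 59.5-fold higher for Gm4779, with an edgeR quasi-likelihood adjusted p of 9.82e-07 for both.

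The libraries labelled Gm1142 knockout did not have fewer Gm1142 counts. Gm1142 had 56, 50 and 41 counts in WT and 65, 46 and 50 in these libraries, or 9.80 ± 0.946 against 11.7 ± 0.988 CPM (SD, n = 3 each). The log2 fold change was 0.25 (SE 0.30, edgeR adjusted p = 0.624). Gm4779 had 42, 48 and 53 counts in WT and 88, 61 and 59 in the libraries labelled Gm1142 knockout, or 9.64 ± 1.69 against 15.1 ± 2.30 CPM. Its log2 fold change of 0.65 (SE 0.30) did not pass the test (edgeR adjusted p = 0.146). A count summed over a gene does not see a small deletion or a frameshift, so it neither checks nor contradicts the Gm1142 label. Each direction given below for this group is that of libraries known by their label alone.

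**Figure D1:**
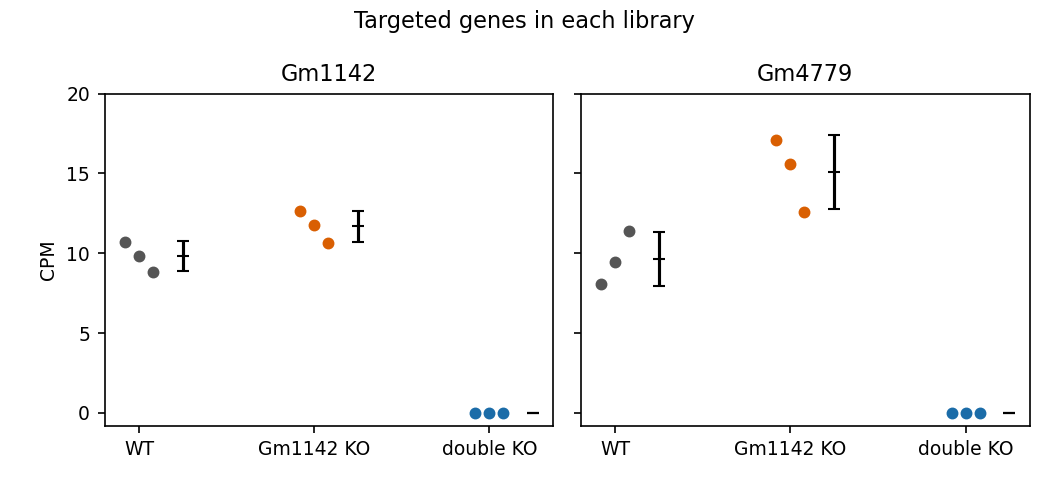
TMM-scaled CPM of Gm1142 and Gm4779 in each of the 9 libraries, with the group mean and SD drawn beside the points. The 3 double-knockout libraries sit at 0 for both genes, and the 3 libraries labelled Gm1142 knockout reach means of 11.7 and 15.1 CPM against 9.80 and 9.64 CPM in WT.

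The libraries labelled Gm1142 knockout stood apart from the other 6. On the first principal component, which held 37.2% of the variance, they scored 43.7 to 67.5, while WT scored -30.7 to -25.2 and the double knockout -34.0 to -21.6. Across genes, Spearman's rho was 0.918 to 0.942 between these libraries and WT, 0.957 to 0.969 between the double knockout and WT, and 0.969 to 0.974 within WT. Mitochondrially encoded genes took 35.6% ± 3.22 of the counts in the libraries labelled Gm1142 knockout (SD, n = 3), 30.7% ± 1.73 in WT and 29.9% ± 2.89 in the double knockout. The highest share, 38.9%, was in replicate 2 of the libraries labelled Gm1142 knockout. That library also had the lowest Actb, at 172 CPM, against 238 to 396 CPM in the other 8.

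**Figure D2:**
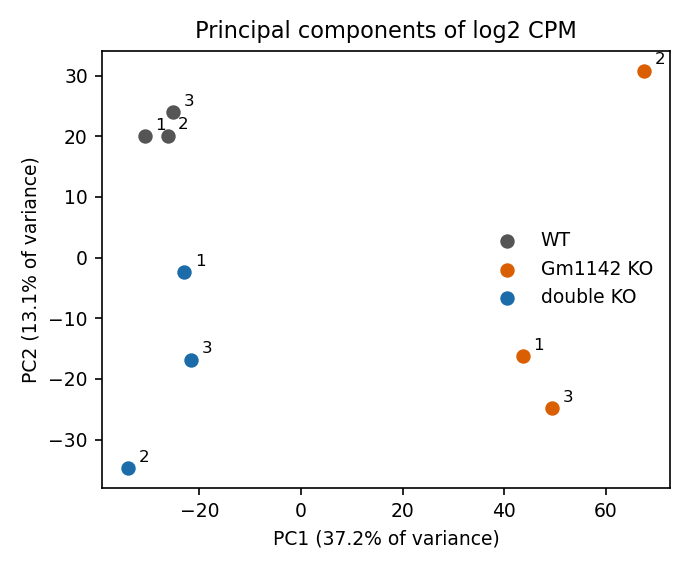
Scores of the 9 libraries on the first 2 principal components of log2 CPM, which held 37.2% and 13.1% of the variance, with replicate numbers beside the points. The 3 libraries labelled Gm1142 knockout lie at 43.7 or more on the first component, and the other 6 at -21.6 or less.

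In the libraries labelled Gm1142 knockout, transcripts of Sertoli and Leydig cell genes were lower than in WT and mitochondrially encoded transcripts were higher, by camera at its preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.628 for each). Of 28 measured Sertoli-cell genes, 11 fell, 1 rose and 16 did not pass (13 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.45. Sox9, a transcription factor that specifies Sertoli cells, went from 51.8 ± 3.76 to 18.5 ± 6.23 CPM, a log2 fold change of -1.47 (SE 0.23, edgeR adjusted p = 1.56e-04). Its relative Sox8 changed by -1.15, the actin-bundling protein gene Espn by -0.91 and the cystatin gene Cst9 by -0.75. Of 17 Leydig-cell genes, 3 fell and 1 rose (4 lower and 1 higher adjusted over the list alone), with a median of -0.55. Fdxr, which passes electrons to mitochondrial steroid-synthesis enzymes, fell from 246 ± 15.9 to 105 ± 8.87 CPM (log2 fold change -1.23, SE 0.12). Cyp17a1, an enzyme of androgen synthesis, fell by 2.64 on the log2 scale (SE 0.54, edgeR adjusted p = 0.00162), though WT itself varied (123 ± 66.2 CPM). Hsd3b1, another steroid-synthesis enzyme, changed by -0.67, and Akr1cl rose by 0.53.

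Of the 10 measured mitochondrially encoded genes, 8 rose and none fell (10 higher adjusted over the list alone), with a median of 0.50. mt-Nd2, a subunit of respiratory complex I, rose by 0.70 (SE 0.12), and the much larger changes of mt-Nd3, mt-Co3 and mt-Nd4l are described with their nuclear copies below. Counts of those genes are uncertain. Of the other 7 members 5 rose, with a median of 0.34, and no list test without the uncertain genes is given here. Among 31 nuclear genes of oxidative phosphorylation, 10 rose and 4 fell (11 and 4 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.894 with an estimated correlation). Cox5a rose by 1.47, Atp5j2 by 1.18 and Atp5l by 0.89, while Ndufa6 changed by -0.78. Of 15 heat-shock genes 4 fell and none rose (also 4 adjusted over the list alone), with a median of -0.47 (0.780 with an estimated correlation), among them the chaperone genes Hsph1 (-1.02) and Chordc1 (-0.77). Hspa5 (-0.78) passed with edgeR but not with DESeq2 (adjusted p = 0.0638). The call of Hspa8 (-0.53) was lost without WT 1 (edgeR adjusted p = 0.08), without WT 3 (0.0728) and without replicate 2 of the libraries labelled Gm1142 knockout (0.0765).

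The 5 lists passed camera with its preset correlation, with adjusted p = 4.21e-04 for Sertoli, 0.0154 for Leydig, 1.16e-09 for mitochondrially encoded, 0.0154 for nuclear oxidative phosphorylation and 0.0306 for heat-shock genes. None passed with an estimated correlation, where the adjusted p was 0.628 for Sertoli, 0.628 for Leydig, 0.628 for mitochondrially encoded, 0.894 for oxidative phosphorylation and 0.780 for heat shock. Other splits of the same 6 libraries called 0 to 8 lists at the preset correlation. Without replicate 2 of the libraries labelled Gm1142 knockout, which had the highest mitochondrial share, 3 lists were called. The call of nuclear oxidative phosphorylation was then lost (camera adjusted p = 0.141), and that of heat shock was lost there (0.101) and without WT 1 (0.0881).

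Across all genes, 3196 genes were called, 1751 higher and 1445 lower, and 1092 of them changed at least 2-fold. Nck2, which encodes an adaptor protein of tyrosine kinase signalling, rose from 15.9 ± 2.29 to 141 ± 22.4 CPM (log2 fold change 3.14, SE 0.18, edgeR adjusted p = 1.83e-10). Cdk1, the kinase that drives entry into mitosis, rose from 64.4 ± 3.74 to 163 ± 20.2 CPM (1.34, SE 0.14). Of 24 proliferation genes 3 rose and 4 fell (4 and 4 adjusted over the list alone), and the list was not called (camera adjusted p = 0.921). Nr4a1, an orphan nuclear receptor of the immediate early class, fell from 157 ± 15.1 to 25 ± 1.99 CPM (log2 fold change -2.64, SE 0.19, edgeR adjusted p = 1.28e-08). Klf6 of the same list changed by -1.25. Fos was higher by 2.29, but this rested on replicate 1 of the libraries labelled Gm1142 knockout, without which it was 1.10 (edgeR adjusted p = 0.265). The germ-cell RNA-binding protein gene Dazl changed by -0.66, the cholesterol-feedback gene Insig1 by 1.09 and the ribosomal protein gene Rps18 by 0.94.

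Tigit, an immune receptor gene, had 0 counts in WT and 5.51 ± 1.37 CPM in the libraries labelled Gm1142 knockout, at least 27.5-fold higher. Tex45, Mir7682, Lrrc75aos1, Ftcd, Cabp4 and Mir143 rose by 2.60 to 3.40 from 2.46 CPM or less in WT. Hist1h2be, Veph1, Zfp54, Hdhd3, Zfp872 and Zbtb8b had log2 fold changes of -3.35 to -2.70. Meox2 (-3.69) and Dmrta2os (-3.10) lost the call without replicate 3 of the libraries labelled Gm1142 knockout (edgeR adjusted p = 0.0566 and 0.0711). Tmem266 (2.89), Rinl (-3.47), BC030343 (-3.39), Npy6r (-2.88) and Cst13 (-2.70) lost it without any of several libraries. Their highest edgeR adjusted p was 0.0694 for Tmem266 (without WT 1), 0.126 for Rinl (without replicate 3 of the libraries labelled Gm1142 knockout), 0.146 for BC030343 (without replicate 1 of them), 0.174 for Npy6r (without WT 1) and 0.265 for Cst13 (without WT 3). Reads of the antisense genes Lrrc75aos1 and Dmrta2os and of the short microRNA genes cannot be told from those of genes that overlap them, since the strand setting was not given in the sources used here. Several abundant genes outside the naming rule also changed and were chosen after their values were seen. The splicing factor gene Srsf6 fell by 1.38 and the histone methyltransferase gene Ezh2 by 1.98 on the log2 scale, and Prrc1 rose by 2.07. Without WT 1, 2037 genes were called in place of 3196.

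In the double knockout, germ-cell transcripts were higher than in WT and transcripts of epididymis and ducts were lower by camera at its preset correlation, by amounts that few single genes passed alone. Neither list passed camera with an estimated correlation (adjusted p = 0.0516 for germ-cell genes and 0.0539 for epididymis and ducts). Of 19 genes expressed across germ-cell stages, 1 rose with all genes tested (13 adjusted over the list alone), with a median log2 fold change of 0.55. Dazl went from 195 ± 27.0 to 348 ± 36.7 CPM, a log2 fold change of 0.83 (SE 0.14, edgeR adjusted p = 0.0069). Of 35 genes of meiotic entry and early prophase, 1 rose (13 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 0.0595 with an estimated correlation). This was Sycp1, a component of the synaptonemal complex, which went from 36.8 ± 6.76 to 78.7 ± 14.3 CPM (log2 fold change 1.10, SE 0.17, edgeR adjusted p = 0.0028). Of 22 genes of the piRNA pathway, which silences transposons in germ cells, Fkbp6 rose from 18.8 ± 1.17 to 36.1 ± 2.12 CPM (0.94, SE 0.18, edgeR adjusted p = 0.0368), and 11 were higher adjusted over the list alone, with a median of 0.49 (camera adjusted p = 0.0539 with an estimated correlation). The deubiquitinase gene Uchl1, which is abundant in spermatogonia, rose from 51.7 ± 0.950 to 88.2 ± 4.01 CPM (0.77, SE 0.14, edgeR adjusted p = 0.0177).

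Among other germ-cell lists, 2 passed camera at its preset correlation with no member passing by itself. Neither passed with an estimated correlation (adjusted p = 0.0516 for X-linked and 0.0949 for differentiating genes), and the differentiating list also missed with fry (0.0508). The 18 X-linked germ-cell genes had a median of 0.67 (10 higher adjusted over the list alone). Taf7l was at 0.69 (SE 0.15, edgeR adjusted p = 0.0932) and Nxf2 at 0.78 (SE 0.18, 0.119). The 15 genes of differentiating spermatogonia had a median of 0.60 (5 higher adjusted over the list alone), with the receptor gene Kit at 0.78 (SE 0.20, edgeR adjusted p = 0.182), Dmrtb1 at 1.75 (SE 0.46, 0.209) and Stra8, a gene induced by retinoic acid, at 0.97 (SE 0.28, 0.264). The 19 markers of undifferentiated spermatogonia did not pass as a list (median 0.12, camera direction down, adjusted p = 0.665), and neither did the 28 Sertoli-cell genes (median -0.08, 0.165) or the 17 Leydig-cell genes (median -0.10, 0.0645). Several of these genes stand in more than 1 list: 11 of the 19 germ-cell genes and 12 of the 22 piRNA genes do.

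The 15 genes of epididymis and ducts had a median of -0.58 with no member called (4 lower adjusted over the list alone), with Cdh16 at -1.26 (SE 0.27, edgeR adjusted p = 0.0816), Hoxa9 at -0.87 (SE 0.24, 0.241) and Emx2 at -1.30 (SE 0.38, 0.265). The 20 genes of steroid and cholesterol synthesis had a median of 0.30 (5 higher adjusted over the list alone, camera adjusted p = 0.0589 with an estimated correlation), with Insig1 at 0.61, Fdft1 at 0.69 and Mvd at 0.99, none of which passed. Other shifts, called at the preset correlation alone, were found for 8 Y-linked genes (median 0.31, 2 higher adjusted over the list alone), 20 genes of stroma and collagen (-0.12, none), 16 endothelial genes (-0.24, 1 lower adjusted over the list alone) and 24 proliferation genes (0.12, none). Their members nearest to passing were Uba1y (0.88, SE 0.18), Tcf21 (-0.48, SE 0.16), Vwf (-1.29, SE 0.37) and Cdc20 (0.37, SE 0.16). The mitochondrially encoded list was called higher by camera at its preset correlation although its median was -0.04, and it did not pass with an estimated correlation (adjusted p = 0.131) or with fry (0.0675). Its mean of 1.48 came from mt-Nd3, mt-Co3 and mt-Nd4l, the 3 members that passed.

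With the preset correlation, 12 of 30 lists passed camera in this comparison. The adjusted p was 7.98e-16 for germ-cell and for meiotic genes, 3.02e-12 for piRNA, 4.11e-12 for X-linked germ-cell, 6.03e-07 for differentiating, 8.93e-08 for epididymis and duct, 2.16e-07 for steroid and cholesterol and 1.35e-09 for mitochondrially encoded genes. It was 0.0118 for Y-linked, 0.0169 for stroma, 0.0491 for endothelium and 0.0490 for proliferation genes. The last 2 were not called with RLE size factors (0.0559 for both), the strict filter (0.0648 and 0.0543), the replicate block (0.0507 for both) or without mitochondrial genes and copies (0.0538 for both), nor endothelium with the compared groups fitted alone (0.0575). None passed with an estimated correlation, where the adjusted p was 0.0516 for germ-cell, 0.0595 for meiotic, 0.0539 for piRNA, 0.0516 for X-linked germ-cell and 0.0949 for differentiating genes. It was 0.0539 for epididymis and ducts, 0.0589 for steroid and cholesterol, 0.131 for mitochondrially encoded, 0.144 for Y-linked, 0.728 for stroma and for proliferation and 0.674 for endothelium. With fry 6 of the 12 passed, the germ-cell, meiotic, piRNA, X-linked germ-cell, epididymis and duct, and steroid and cholesterol lists (adjusted p = 0.0149 to 0.0215). Other splits of the same 6 libraries called 1 to 14 lists at the preset correlation. Leaving out 1 library ended the camera call of Y-linked genes (without WT 3, adjusted p = 0.0907) and of stroma (without WT 1, 0.186, and double-knockout 3, 0.817). It also ended that of endothelium (without WT 3, 0.429, and double-knockout 2, 0.144, or 3, 0.0654) and of proliferation (without WT 2, 0.0727, and WT 3, 0.281). Without double-knockout 2 the proliferation list turned to a mean of -0.01.

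**Figure D3:**
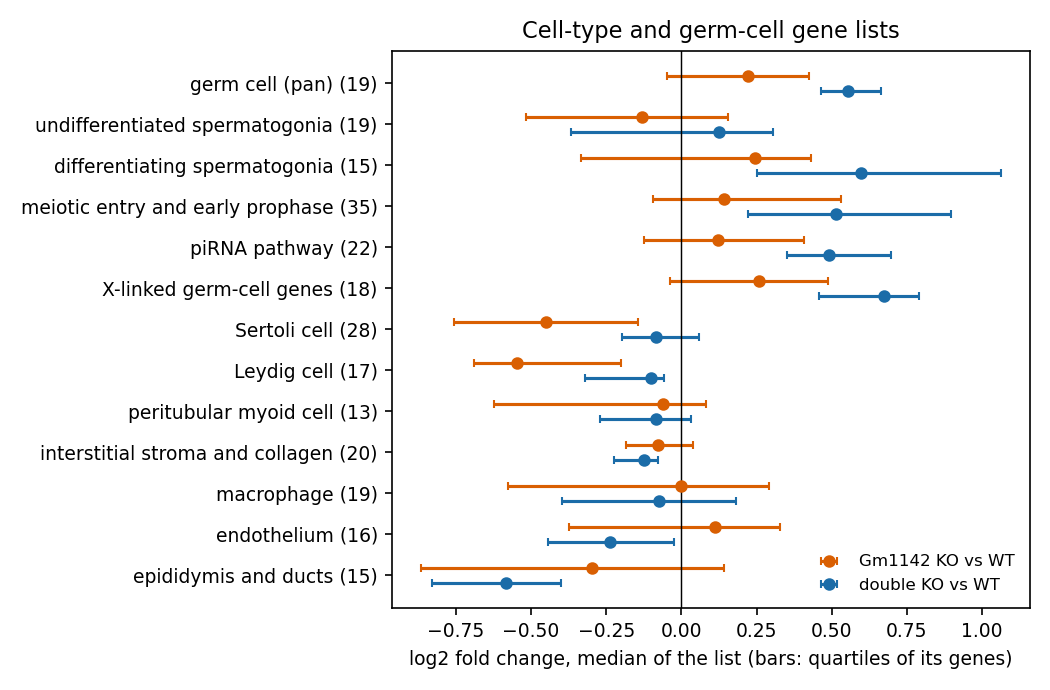
Median log2 fold change of 13 cell-type and germ-cell gene lists against WT, for the libraries labelled Gm1142 knockout and for the double knockout, with bars from the lower to the upper quartile of the list's genes and the number of measured genes in parentheses. Of the 6 germ-cell lists shown, 5 have medians of 0.49 to 0.67 in the double knockout and undifferentiated spermatogonia 0.12. The lists of pachytene spermatocyte and spermatid genes (0.09 and 0.30) are not drawn, and Sertoli and Leydig medians lie at -0.45 and -0.55 in the libraries labelled Gm1142 knockout.

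Across all genes, 16 were called in the double knockout, 8 higher and 8 lower, including both targets. Nr4a1 was lower here too, at 54.6 ± 19.2 CPM against 157 ± 15.1 in WT (log2 fold change -1.54, SE 0.18, edgeR adjusted p = 1.05e-04). The homeobox gene Hoxd3 fell from 37.0 ± 6.87 to 14.2 ± 2.12 CPM (-1.40, SE 0.21, edgeR adjusted p = 0.0028). Odf3b had 0 counts in the double knockout and 3.05 ± 1.82 CPM in WT, at least 18.8-fold higher, and lost the call when any 1 of the 6 libraries was left out (edgeR adjusted p = 0.0660 without WT 3 to 0.209 without double-knockout 2). Gm47283, chosen after its value was seen, rose by 1.24 (edgeR adjusted p = 0.0039) and was not called without WT 1 (0.0646) or WT 2 (0.0715). The remaining 6 of the 16 are the mitochondrial genes and nuclear copies described below. The germ-cell calls also depended on single libraries. Sycp1 lost its call without WT 1 (edgeR adjusted p = 0.0717). Dazl lost it without WT 1 (0.167), WT 3 (0.114) or double-knockout 2 (0.0608). Uchl1 lost it without any 1 library except double-knockout 1 (0.0669 to 0.230), and Fkbp6 without any 1 of the 6 (0.0840 to 0.306). In total 9 genes were called without WT 1 and 32 without double-knockout 1, and 58 were called with DESeq2, 110 with no filter on low counts and 28 when the double knockout and WT were fitted alone.

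In both knockout groups 3 mitochondrially encoded genes rose and their near-identical copies in the nuclear genome fell. mt-Nd3, a subunit of respiratory complex I, went from 0.550 ± 0.478 CPM in WT to 56.7 ± 4.59 in the libraries labelled Gm1142 knockout and 40.6 ± 13.7 in the double knockout. Its copy Gm28438 went from 105 ± 24.2 to 1.06 ± 0.432 and 0.507 ± 0.393 CPM. mt-Co3, a subunit of cytochrome c oxidase, went from 0.458 ± 0.635 to 10.8 ± 4.51 and 13.5 ± 2.92 CPM, and its copy Gm28437 from 21.2 ± 6.68 to 0.442 ± 0.0630 and 0.240 ± 0.209. mt-Nd4l went from 0.201 ± 0.0125 to 4.57 ± 1.83 and 4.35 ± 2.71 CPM, and its copy Gm10222 from 9.27 ± 4.37 to 0.15 ± 0.133 and 0.189 ± 0.236. The copies lie on chromosome 1 and were named after their values were seen. In the reference, the exonic sequence of Gm28438 differs from mt-Nd3 at 1 of 345 bases, and Gm28437 and Gm10222 match over 783 and 294 bases without a difference. Counts of each member are therefore uncertain, because the assignment of reads between them depends on how multiply mapped reads were handled. Against WT, the log2 fold changes of the mitochondrial genes were 6.66, 4.48 and 4.37 in the libraries labelled Gm1142 knockout and 6.17, 4.78 and 4.25 in the double knockout (SE 0.39 to 0.75). The call of mt-Nd4l in the double knockout (edgeR adjusted p = 0.0176) was lost without WT 1 (0.188), WT 2 (0.113), WT 3 (0.114) or double-knockout 3 (0.106), and with limma-voom (0.126). The other 7 mitochondrial protein genes had log2 fold changes of -0.11 to 0.03 in the double knockout, none of them called, and 0.26 to 0.70 in the libraries labelled Gm1142 knockout, 5 of them called.

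**Figure D4:**
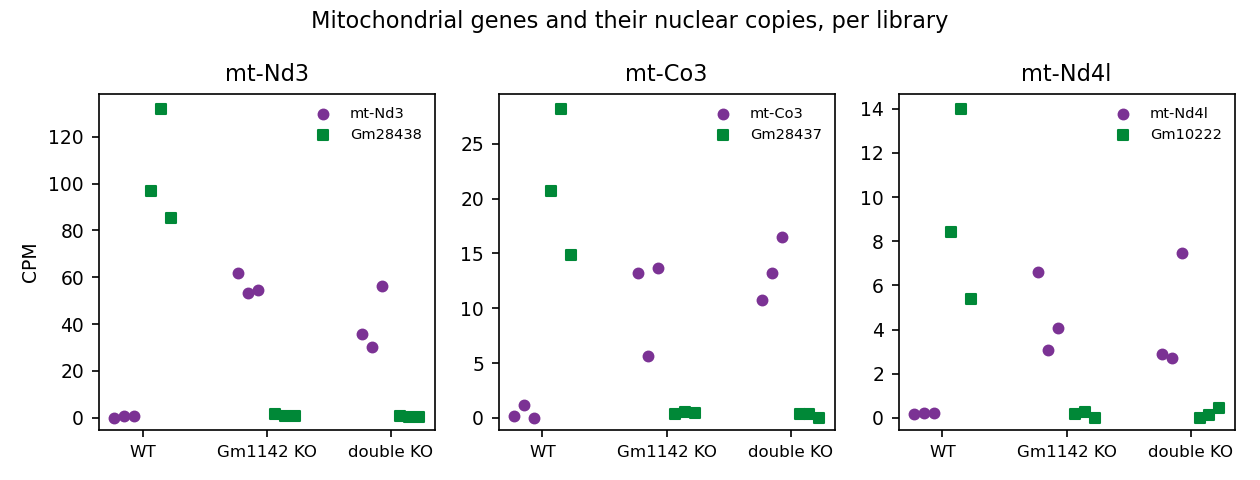
CPM of 3 mitochondrially encoded genes (circles) and their nuclear copies (squares) in each library, by group, on separate linear axes. In WT the copies hold the counts (means of 105, 21.2 and 9.27 CPM) and in both knockout groups the mitochondrial genes do.

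Between the knockout groups, the double knockout had higher transcripts of Sertoli-cell and germ-cell genes than the libraries labelled Gm1142 knockout, and lower transcripts of oxidative phosphorylation, mitochondrially encoded and erythroid genes, by camera at its preset correlation. None of these lists passed with an estimated correlation (adjusted p = 0.660 for each). Of 28 Sertoli-cell genes 13 rose and 1 fell (also 13 and 1 adjusted over the list alone), with a median of 0.45. Sox9 rose by 1.25 (SE 0.23), Sox8 by 1.13 (SE 0.19), Cst9 by 0.80 and Espn by 0.78. Of 19 germ-cell genes 5 rose and none fell (6 higher adjusted over the list alone), with a median of 0.34. Dazl was at 348 ± 36.7 against 124 ± 18.7 CPM, a log2 fold change of 1.49 (SE 0.14, edgeR adjusted p = 3.94e-07). Of 35 meiotic genes 7 rose and 1 fell (also 7 and 1 adjusted over the list alone), of 22 piRNA genes 6 rose (7 adjusted over the list alone), of 18 X-linked germ-cell genes 4 rose (6) and of 15 genes of differentiating spermatogonia 4 rose (4), with medians of 0.37, 0.40, 0.43 and 0.44. Fkbp6 rose by 0.81 (SE 0.18), Tex15, which acts in piRNA-directed silencing, by 0.90 (SE 0.21), Nxf2 by 0.75 (SE 0.18) and Kitl, the Sertoli-cell ligand of Kit, by 0.86 (SE 0.17). Kitl stands in both the Sertoli-cell list and the list of differentiating spermatogonia, so its rise does not speak for germ cells. Of 31 oxidative phosphorylation genes 10 fell and 2 rose (also 10 and 2 adjusted over the list alone), with a median of -0.24. Of 10 mitochondrially encoded genes 7 fell (8 adjusted over the list alone), with a median of -0.42. Cox5a was at -1.45, Atp5j2 at -1.29, Cox6c at -1.11 and mt-Nd2 at -0.67. Of 7 erythroid genes Fech (-0.79), Hba-a2 (-1.10) and Hba-a1 (-0.83) fell (also 3 adjusted over the list alone). The globin genes are near-identical copies whose reads can be split, and the call of Hba-a1 was lost without double-knockout 2 (edgeR adjusted p = 0.0653).

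These 9 lists passed camera with the preset correlation, at adjusted p = 0.00874 for Sertoli-cell, germ-cell, mitochondrially encoded and oxidative phosphorylation genes, 0.0107 for piRNA, 0.0187 for meiotic, 0.0192 for X-linked germ-cell, 0.0271 for differentiating and 0.0383 for erythroid genes. The differentiating list was not called with the strict filter (0.0643), and none of the 9 passed with fry (0.0540 to 0.0797). With an estimated correlation the adjusted p was 0.660 for each of the 9, and other splits of the same 6 libraries called 0 to 11 lists at the preset correlation. Leaving out 1 library ended the camera call of differentiating genes (without replicate 2 of the libraries labelled Gm1142 knockout, adjusted p = 0.0525, and double-knockout 2, 0.0504, or 3, 0.0503) and of X-linked genes (without double-knockout 3, 0.0536). It ended that of meiotic genes (without replicate 1 of the libraries labelled Gm1142 knockout, 0.0611, and double-knockout 3, 0.0806) and of erythroid genes (without the same replicate 1, 0.128, and double-knockout 2, 0.0876, or 3, 0.0688). Without double-knockout 2 and replicate 2 of the libraries labelled Gm1142 knockout, a setting chosen after the data were seen, 4 lists were called, Sertoli-cell and meiotic genes among them. The other 7 then had camera adjusted p = 0.0526 to 0.123, and Tex15 (edgeR adjusted p = 0.105), Nxf2 (0.0628) and Hba-a2 (0.0525) lost their calls. The mitochondrial share was 29.9% in the double knockout and 35.6% in the libraries labelled Gm1142 knockout.

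In this comparison 3301 genes were called, 1565 higher and 1736 lower in the double knockout. Nabp1, a gene of single-stranded DNA binding, was at 72.5 ± 10.8 against 13.2 ± 6.48 CPM (log2 fold change 2.45, SE 0.23, edgeR adjusted p = 4.35e-07). Zfp54, Inka2, Zfp759, Kctd21, Zbtb8b, Zfp719 and Rasd1 were higher by 2.48 to 3.30. Nck2 was lower by -3.03 (SE 0.17) and Cdk1 by -1.41 (SE 0.14). Odf3b, at 0 counts in the double knockout, was at least 25-fold higher in the libraries labelled Gm1142 knockout. Tex45, Lrrc75aos1, Mir143, Chsy3, Slc17a4 and Fos had log2 fold changes of -4.79 to -3.10. That of Fos (-3.26) rested in part on replicate 1 of the libraries labelled Gm1142 knockout, where it was at 24.7 CPM against 7.41 and 2.98 in replicates 2 and 3. Without it the change was smaller and the gene stayed called. Tigit (-4.12) passed with edgeR and not with DESeq2 (adjusted p = 0.205). Meox2 (3.12), Prss50 (3.02), Zfp712 (2.72), Foxq1 (2.54), Pdzd3 (-2.98), Slc5a2 (-2.95) and Hoxa4 (-2.92) each lost the call without at least 1 library. Their highest edgeR adjusted p was 0.124 for Meox2, 0.0697 for Zfp712 (both without replicate 3 of the libraries labelled Gm1142 knockout) and 0.152 for Foxq1 (without replicate 1 of them). It was 0.0688 for Prss50 and 0.0928 for Slc5a2 (both without replicate 2 of them), and 0.0607 for Pdzd3 and 0.107 for Hoxa4 (both without double-knockout 2). Without double-knockout 2, 2128 genes were called, and 2004 without that library and replicate 2 of the libraries labelled Gm1142 knockout.

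The changes of the 2 knockout groups against WT overlapped in few genes. Across all genes tested, the log2 fold changes had a Pearson r of 0.316, below the 0.502 ± 0.009 (SD, 20 simulations) that unchanged groups sharing the WT libraries gave. Their covariance was 0.0977 against a simulated 0.0645, a difference of 0.0331. The simulations changed no group, while the many changes in the libraries labelled Gm1142 knockout widen their values and lower r. The lower r therefore does not show that the knockout groups are less alike than unchanged groups. Genes called with the same sign in both numbered 11, 6 higher and 5 lower, where no simulation gave any and independent lists would share 0.812 and 0.670. They were mt-Nd3, mt-Co3, mt-Nd4l, Gm47283, Sycp1 and Uchl1 (higher), and Gm28438, Gm28437, Gm10222, Nr4a1 and Hoxd3 (lower). The counts of the mitochondrial genes and nuclear copies among them are uncertain. The call of Sycp1 in the libraries labelled Gm1142 knockout (0.62) was lost without WT 1 (edgeR adjusted p = 0.0971). The count was 7 without WT 1 and 25 without replicate 2 of the libraries labelled Gm1142 knockout. Dazl was called with opposite signs, at -0.66 and 0.83. With 3 WT libraries the controls cannot be split into 2 sets of at least 2, so part of any excess may come from the shared WT libraries.

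Of the 3196 genes called between the libraries labelled Gm1142 knockout and WT, 2225 were also called in the double knockout against the libraries labelled Gm1142 knockout with the opposite sign. These were 1253 higher then lower and 972 lower then higher, where independent lists would share 176 and 131 and the highest of the simulations gave 1. The covariance was -0.392 against a simulated -0.0670, a difference of -0.325, with r = -0.801 against -0.516. Both comparisons share the libraries labelled Gm1142 knockout, whose change from WT enters the second with the opposite sign. With 16 genes called in the double knockout against WT, the 2225 largely restate that the libraries labelled Gm1142 knockout stood apart. The simulations changed no group, and independent lists would share no libraries, so neither is a baseline for this count.

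**Figure D5:**
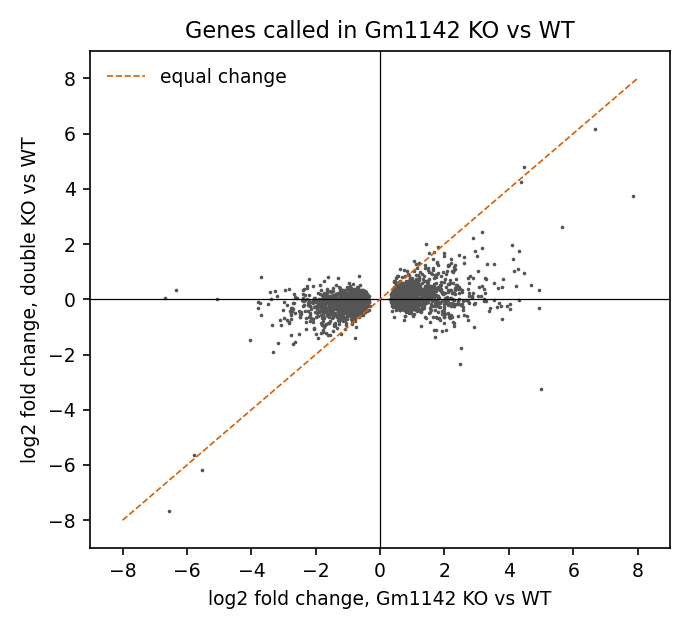
Log2 fold change against WT of the 3196 genes called in the libraries labelled Gm1142 knockout (x axis) and the same genes in the double knockout (y axis), with a dashed line of equal change. Most points lie near 0 on the y axis, with a median of 0.11 when signed by the x axis direction, and few lie on the dashed line.

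The remaining lists were not called by camera in any comparison. Medians in the libraries labelled Gm1142 knockout against WT, and in the double knockout against WT, were 0.43 and 0.09 for 7 pachytene spermatocyte genes and 0.52 and 0.30 for 6 spermatid genes. They were -0.06 and -0.09 for 13 genes of peritubular myoid cells, -0.00091 and -0.07 for 19 of macrophages, 0.27 and -0.17 for 10 of adipose tissue and -0.35 and -0.10 for 9 of skeletal muscle. They were 0.04 and 0.09 for 13 retinoic acid genes, -0.36 and 0.02 for 19 p53 targets, and 0.08 and -0.07 for 21 immediate early and stress genes. For 12 interferon-response genes they were -0.03 and 0.04, for 21 genes of glycolysis and hypoxia -0.25 and -0.05, and for 28 ribosomal protein genes 0.17 and 0.12. The camera adjusted p of these lists was 0.0737 or higher in the 3 comparisons. With fry the p53 targets passed in the libraries labelled Gm1142 knockout against WT (lower, adjusted p = 0.0230) and between the knockout groups (higher in the double knockout, 0.0220), and the ribosomal protein genes in the first of these (higher, 0.0261).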

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

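Removing mitochondrial genes, removing GC and length trends, thinning, and leaving out 2 libraries together were chosen after seeing the data; the other settings were fixed before. Where a result changed with a setting, the cause was not tested unless construction is named. The log2 fold changes of Gm1142 and Gm4779 kept their direction and side of the threshold in all settings run. The 3196 genes called between the libraries labelled Gm1142 knockout and WT became 1092 with a 2-fold minimum, by construction, and the 3301 between the knockout groups 1128. The 16 called in the double knockout against WT became 110 without a filter, 58 with DESeq2, 28 with the compared groups fitted alone and 8 without mitochondrial genes and copies. Of the 16, 6 left that fit by construction, and Fkbp6 and Odf3b lost their calls there (edgeR adjusted p = 0.0744 for both), which was not explained. The 11 called in both groups became 43 without a filter and 32 with DESeq2. Without replicate 2 of both knockout groups, 2004 genes were called between them. With 1 library left out, calls ranged from 2037 to 3015, 9 to 32 and 2128 to 3219 in the 3 comparisons in that order, and from 7 to 25 in both groups. Log2 fold changes against WT in the libraries labelled Gm1142 knockout then ranged from 0.18 to 0.32 for Gm1142 and from 0.53 to 0.78 for Gm4779. In the double knockout both are at 0 counts, so that their folds are lower bounds and only the calls are compared. The highest edgeR adjusted p with 1 library left out was 2.08e-05 for Gm1142 and 2.16e-05 for Gm4779, and limma-voom gave 2.91e-05 and 5.04e-05.

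Camera called 5, 12 and 9 gene lists at its preset correlation and 0, 0 and 0 with an estimated correlation. Fry called 6, 6 and 1, of which 3, 6 and 0 are among the former; its others were the p53 targets, ribosomal protein and Y-linked genes (0.0482) in the first comparison and the p53 targets in the third. With camera 3, 16 and 4 were called without replicate 2 of both knockout groups. With 1 library left out, 3 to 6, 10 to 15 and 6 to 10 lists were called. The proliferation list in the double knockout had means of -0.0125 (without double-knockout 2) to 0.199 (without double-knockout 1), and turned to a camera direction of down (mean 0.000824) without replicate 2 of both knockout groups. Over the other settings, values of named genes kept direction and side 3531 times, lost the call 453 times, 292 of them with 1 library left out, and gained it 22 times. None reversed. Lists kept the call 276 times and lost it 83 times.

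With replicate number as a block, 2921, 16 and 2965 genes and 5, 10 and 9 lists were called. Same-numbered libraries did not deviate together (r = -0.267 to 0.101, above 0.1 in 1 of 9 pairs, with 3 of 9 libraries closest to their own number). At this depth a 2-fold change was called in 48% to 53% of simulated genes.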

Other observations

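The tests in this part were chosen after the results were seen, except the 31 gene lists, which were fixed before. The 10 gene families tested were not among the fixed lists, though some share genes with them. Only zinc-finger genes passed camera in the libraries labelled Gm1142 knockout against WT, and not with an estimated correlation. Of 365 measured zinc-finger (Zfp) genes, most of them transcription factors that bind DNA, 67 fell and 17 rose against WT, with a median log2 fold change of -0.35 (camera adjusted p = 1.12e-04, 0.356 with an estimated correlation). Between the knockout groups 88 were higher and 19 lower in the double knockout (median 0.42, camera adjusted p = 3.64e-05, and 0.362 with an estimated correlation). In the double knockout against WT none was called and the median was 0.04. Transcript classes were counted without a test of the class: of 76 sense-intronic transcripts 22 rose and 8 fell in the libraries labelled Gm1142 knockout (median 0.53, quartiles -0.36 to 1.15), and of 62 snoRNA genes 8 rose and none fell (median 0.52, quartiles -0.12 to 0.91).

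In the double knockout against WT, the 32 measured genes of the Hox clusters, which pattern the body axis and the reproductive ducts, had a median of -0.68 with Hoxd3 called lower (camera adjusted p = 6.52e-15, and 0.0421 with an estimated correlation). The 6 keratin genes had a median of -0.82 (0.00203, and 0.0421 with an estimated correlation) and the 23 histone genes -0.29 (0.00186, and 0.0421). The epididymis and duct list also names Hox genes, such as Hoxa9, and the keratin genes Krt7 and Krt19. The Hox and keratin results may therefore partly repeat that list. The stroma list likewise names collagen genes. The 39 collagen genes (0.0311) did not pass with an estimated correlation (0.721), and neither did the Hox clusters between the knockout groups (0.0170, and 0.383). Of the 20 genes measured within 1000000 bases of the targeted pair in GRCm38, none was called in the double knockout against WT (log2 fold changes of -0.51 to 0.66). In the libraries labelled Gm1142 knockout 2 rose and 3 fell. The largest change was that of Itgb1bp2, named after its value was seen, from 3.84 ± 1.01 to 12.9 ± 2.65 CPM (1.74, SE 0.36, edgeR adjusted p = 0.0017).

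The libraries labelled Gm1142 knockout differed from WT in 3196 genes and the double knockout, which lacks the same gene by label, in 16. If loss of Gm1142 acted alike in both, the 3196 genes would move by similar amounts in the double knockout. Their median change there, signed by the first direction, was 0.108 (quartiles -0.047 to 0.273) against 0.812, which argues against a loss that acts alike, though an effect that loss of Gm4779 cancels stays open. GC and length trends do not account for it, since 3344 genes were called once they were removed. A difference in RNA or library handling of these 3 libraries may contribute, and sense-intronic transcripts had a median of 0.529. Handling cannot be told apart from genotype or litter here because no label separates them. The labels give postnatal day 7 for all libraries, so only an age difference that they do not show stays open.

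The 3 mitochondrial genes and their nuclear copies changed places in both knockout groups. A change of mitochondrial transcription would raise the other mitochondrial protein genes by a similar amount, and the highest of those 7 was at 0.0284 in the double knockout, which argues against it. Assignment of the same reads to one copy or the other would keep the summed CPM of each pair only if reads that map to both were counted. That setting was not given, and where such reads are dropped the sums need not be equal. The sums were 2.56, 1.58 and 2.09 times as high in WT as in the double knockout, while the copies themselves differed 206.5, 88.4 and 49.1 times. In WT the mt-Co3 pair summed to 21.7 CPM, while mt-Co1 alone was at 136566 CPM. The sums therefore do not decide, and a shift of assignment stays open for all or part of the change. A mitochondrial sequence difference between the WT and knockout mice was not tested, since reads were not analysed here.

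Germ-cell genes were higher in the double knockout than in WT, with a median of 0.55. The highest other split of the 6 libraries gave 0.271 in absolute value. Each other split mixes both groups and holds part of any real difference, so that value is no baseline for 0.55. Only 1 of 19 members was called and the list did not pass camera with an estimated correlation (adjusted p = 0.0516), so the change itself is uncertain. A larger share of germ cells of every stage would raise undifferentiated markers as much, and their upper quartile was 0.305 (most abundant, Ddit4 at 233 and Foxo1 at 30.0 CPM in WT, with 2 of 19 genes held by another list). Fewer duct or stroma cells would raise Sertoli-cell markers too, and their upper quartile was 0.0575 (most abundant, Clu at 528 and Inha at 461 CPM in WT, with 1 of 28 genes held by another list). Both values lie below 0.55 and argue against these explanations. For the larger share of germ cells, this holds only where undifferentiated markers are not also expressed by other cells, which was not tested. Germ cells further along in differentiation, by genotype or by age, is a candidate explanation. The 49 differentiating and meiotic genes exceeded 19 undifferentiated genes by a difference of medians of 0.389 (one-sided permutation test over genes, 100000 permutations, p = 0.00276, with genes not independent). Among the 49 is Kitl, which also stands in the Sertoli-cell list. The direction of the permutation test was chosen after the list medians were seen, so it restates that difference and does not decide for the explanation. A litter difference stays open, as does an age difference that the labels, postnatal day 7 for all libraries, do not show.

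Other splits of the 6 libraries of each comparison into 3 and 3 number 10 with the real one, too few for a share under 0.05. For genes called, 1 of the 10 splits in each comparison, the real one, gave as many: the real counts were 3196, 16 and 3301, and the highest of the others 0, 0 and 0. Every other split mixes both groups, so a real difference widens its spread and lowers its calls. These counts are therefore no baseline of unchanged groups. For lists called at the preset correlation, 5 of 10 splits gave as many as the real 5 in the libraries labelled Gm1142 knockout against WT (highest other 8). In the double knockout against WT 3 of 10 gave as many as the real 12 (highest other 14), and between the knockout groups 3 of 10 gave as many as the real 9 (highest other 11). Groups that mix both labels thus called as many lists at the preset correlation as the real ones in several splits. They hold part of any real difference, so they are not unchanged groups either.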
